A study of Mus musculus with 2 samples.

How the data were processed

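Total RNA from dissected mouse retinas at postnatal day 12 was measured on 1-colour Agilent expression arrays, with 1 array for the group labelled wild type and 1 for the group labelled Samd7 knockout. Per the labels' protocols, RNA was amplified and labelled with the dye Cy3 with a low-input kit. The labels do not say how many animals or retinas went into each RNA sample, nor which part of Samd7 had been deleted.

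Scanner signals are linear intensity values that the authors deposited as written by Agilent Feature Extraction version 11.5.1.1 with protocol GE1_1105_Oct12, per the file headers. Background subtraction and spatial detrending are among the steps for which the software recorded statistics, per the file headers. The array design was built on mouse assembly mm9, and both arrays lay on 1 slide, so slide does not separate the groups. The deposited value table of the authors holds, for each array, these processed intensity values multiplied by a constant: the log2 ratio of the table's value to the scanner's processed signal had a median of 1.31 on the wild-type-labelled array and 1.37 on the knockout-labelled array. The rule behind the constant is not given in the sources used here. The table served only as an alternative.

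Each array held 62976 features, of which 59305 were non-control spots for 55681 distinct probes. No spot was saturated. Spots well above background, by the scanner's own call, numbered 35745 (60.3%) on the wild-type-labelled array and 36143 (60.9%) on the knockout-labelled array, and 34551 were so on both. Outlier flags removed 119 and 163 non-control spots, respectively. The median processed signal was 43.5 on the wild-type-labelled array and 41.0 on the knockout-labelled array, and the 75th percentile was 574 and 554, respectively. Across spots above background on both arrays, Pearson's r of the log2 signals was 0.994; this is a correlation across spots, which are not independent replicates.

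Values were log2 processed signal minus the array's 75th percentile over non-control spots. Flagged spots were left out, and spots of the same probe were averaged on the log2 scale. Probes were named through their transcript accession, without version, in a RefSeq gene table of assembly GRCm38.p6, which was used for names and gene order only. Of 55677 probes left, 28330 (50.9%) had 1 symbol, none had several and 27347 were unnamed here, which gave 21367 symbols. The brightest probe stood for a gene, and a gene was counted when above background on at least 1 array. Where a gene was above background on 1 array only, its difference is a bound, taken against the higher of that other array's lowest signal called well above background and the gene's own dim signal there. Such a bound allows nothing for spot noise, so a fold given as at least a value refers to the main values only. All differences are log2 signal on the knockout-labelled array minus log2 signal on the wild-type-labelled array.

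There were no replicates, so no p-value, standard error or spread between animals exists, and each difference compares these 2 arrays. Precision within an array was taken from 294 probes with repeated spots, whose log2 difference had a pooled SD of 0.05 at signals of 0 or more, 0.09 from -2 to 0, 0.19 from -4 to -2 and 0.37 below -4. Among 4131 genes with at least 2 probes above background on both arrays, the median range of the difference between probes was 0.10. Of the 49 such genes that differed at least 2-fold, 44 had all probes on the same side and 5 had opposed probes (Adamtsl5, Arhgap4, Calr3, Ldb3 and Uty). In only 33 of the 49 were all probes at least 2-fold apart in the same direction.

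The threshold for counting a gene was 2-fold. The 25 gene lists, covering retinal cell types, neighbouring tissues, Polycomb complexes and cell states, were fixed before the data were examined, as were the threshold, the main values, the alternatives and the naming rule, except where stated. A list's median difference was placed among the medians of 10000 random lists of the same size matched on mean signal in 20 bins; the percentile describes these 2 arrays and is not a test across animals. With 25 lists, 5 fell under the 2.5th percentile and 7 over the 97.5th. Named genes were Samd7, the 15 highest and 15 lowest genes measured on both arrays with the same sign under every normalization and in every probe, the 5 largest bounds each way, and from each list the 2 highest and 2 lowest of the members measured on both arrays and all members at least 2-fold apart. Clone names, predicted genes and genes known by accession only were left out of that rule. Other list members are given as examples, and genes named outside the rule are identified as such. A member of the rod list is not reported here by itself.

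The counting step was run on simulated signals for 15577 genes of this comparison. It called 0 of 67 genes changed 1.5-fold, 66 of 67 changed 2.5-fold (98.5%), 66 of 66 changed 4-fold and 3 of 15377 unchanged genes. The list step placed 7 of 200 unshifted lists of 20 genes outside the central range and all 50 lists shifted by 0.3. These runs model spot noise only. All genes scored in the counting step were above background on both simulated arrays. Calls by a bound, 92 of the higher and 124 of the lower genes in the data, were therefore not simulated.

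Alternatives were quantile normalization, median centring, intensity-dependent loess, the authors' value table, other filters on dim probes, the mean over a gene's probes, thresholds of 1.5-fold and 4-fold, and unmatched random lists. Background correction by normexp had been planned on mean signals, but the scanner files used here hold no mean-signal column. It was therefore run on median signals with an offset of 50, a choice made after seeing the data. The offset is added to every signal, and the median processed signal was 43.5 on the wild-type-labelled and 41.0 on the knockout-labelled array. Normexp thus pulls the differences of dim genes toward 0 by arithmetic, whatever their true size. Every scaling moved the median difference of spots above background on both arrays by less than 0.1, from -0.021 under the main values to 0.001 under loess. Calculations used R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.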

Results

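Gene expression was compared between 1 retina RNA sample labelled wild type and 1 labelled Samd7 knockout, both from mice at postnatal day 12, when photoreceptors are still maturing. Samd7 encodes a sterile alpha motif domain protein made in photoreceptors. The comparison asks how the retinal expression profile differs between the genotypes. Of the named genes, 15934 were above background on at least 1 array, 15256 of them on both.

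The targeted gene came out higher, not lower, on the array labelled knockout. Samd7 is represented by 1 named probe, A_55_P2138237, and whether any unnamed probe also covers the gene is not known here. The log2 signal of the named probe relative to the array's 75th percentile was 4.68 on the wild-type-labelled array and 6.47 on the knockout-labelled array. The difference of 1.78 is 3.44-fold, against a technical SD of 0.05 at this signal. Its measured value thus goes against the label, unless the probe lies outside the deleted part of the gene, in which case it checks nothing; the position of the probe within Samd7 and the extent of the deletion are not known here. The arrays are therefore called wild-type-labelled and knockout-labelled throughout, and each direction below rests on those labels.

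On the knockout-labelled array, part of the cone photoreceptor program and nearly all lens crystallins were several-fold higher, while rod genes were lower as a group. The cone cyclic nucleotide-gated channel subunit Cnga3 was 7.50-fold higher, the short-wavelength opsin Opn1sw 4.27-fold higher and the lens crystallin Cryaa 4.77-fold higher. The rod transducin Gnat1 was 4.38-fold lower. The highest difference among named genes was that of the zinc-finger transcription factor Insm2, at 74.4-fold (46.6-fold with the mean over its probes). Markers of inner retinal neurons differed little as groups.

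In all, 252 genes (1.58%) were at least 2-fold higher on the knockout-labelled array, 160 of them measured on both arrays and 92 by a bound. Another 218 (1.37%) were at least 2-fold lower, 94 measured on both arrays and 124 by a bound. At 4-fold the numbers were 79 higher and 58 lower, and at 8-fold 19 and 6. Of the genes measured on both arrays, 14450 (94.7%) lay within 0.5 of 0 on the log2 scale. Most genes counted in either direction were dim, the lower ones more so. With only genes whose mean signal reached the median, 69 of the 252 higher and 14 of the 218 lower genes were left. After normexp background correction on median signals, whose offset shrinks dim differences, 120 were higher and 45 lower.

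**Figure D1:**
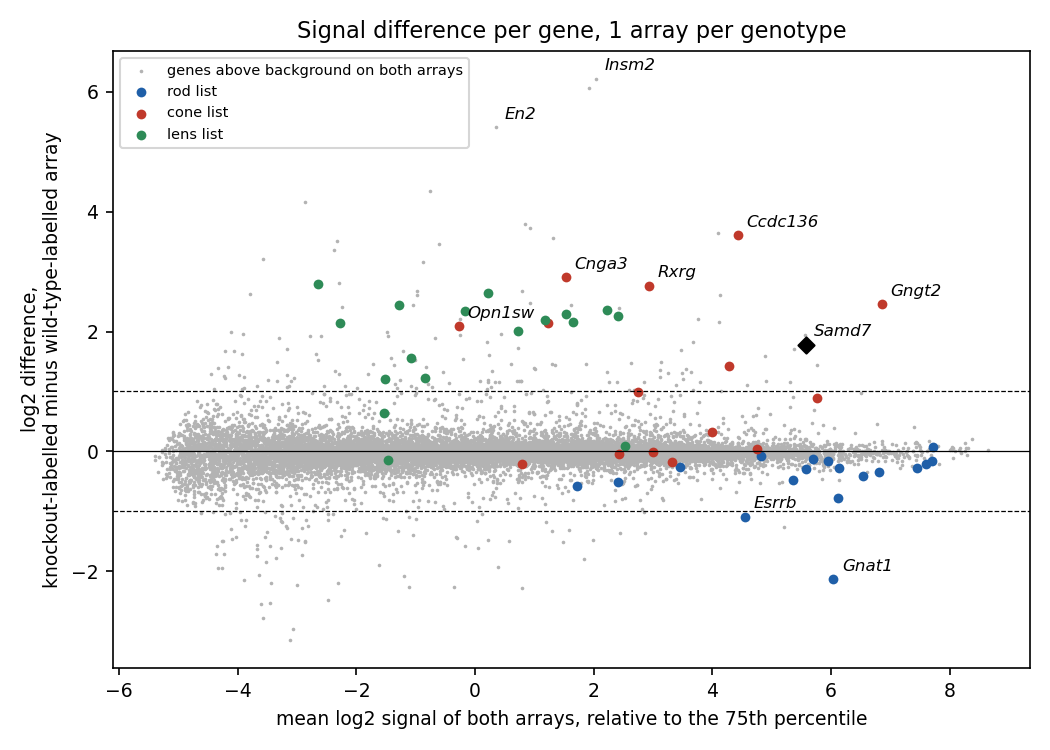
Log2 signal difference (knockout-labelled minus wild-type-labelled array, vertical axis) against the mean log2 signal of both arrays relative to the 75th percentile (horizontal axis). Each grey point is a gene above background on both arrays, coloured points are members of the rod, cone and lens lists, the diamond is Samd7 at 1.78, and dashed lines mark 2-fold; there is 1 array per genotype and no error between animals.

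Cone genes differed unequally, from several-fold higher on the knockout-labelled array to level. The median difference of the 15 cone genes was 0.997 on the log2 scale, above all 10000 matched random lists, with 7 members at least 2-fold higher and none 2-fold lower. These were Ccdc136 (3.61), Cnga3 (2.91), Rxrg (2.77), a retinoid X receptor of cones, the cone transducin gamma subunit Gngt2 (2.45), the channel subunit Cngb3 (2.14), Opn1sw (2.09) and the potassium channel subunit Kcne2 (1.42). The other Rxrg probe gave 1.23, and the mean over both was 3.99-fold. Otop3 lay just under 2-fold at 0.997, and the cone transducin beta subunit Gnb3 was at 0.89. By contrast, 5 members lay below 0.25: the cone transducin alpha subunit Gnat2 (0.04), the cone phosphodiesterase subunits Pde6h (-0.01) and Pde6c (-0.04), the medium-wavelength opsin Opn1mw (-0.17), and the thyroid hormone receptor Thrb (-0.21). Cone arrestin, Arr3, lay in between at 0.32.

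Rod genes were lower on the knockout-labelled array in 17 of 18 cases. Their median difference was -0.29, below all 10000 matched random lists. Gnat1 (-2.13) and the orphan nuclear receptor Esrrb (-1.09) were the only members at least 2-fold lower. Without Gnat1 the median was still -0.28. The rod-specifying transcription factors Nrl (-0.16) and Nr2e3 (-0.13) were close to level, and the disc protein Rom1 was the single member on the other side at 0.08. Genes used by rods and cones alike had a median of -0.21, also below all 10000 random lists, with 27 of 32 lower. Guca1b, a guanylate cyclase activator, was the only member at least 2-fold lower (-1.33, with -2.07 in its other probe), whereas the related Guca1a was at 0.38 and Impg1, of the interphotoreceptor matrix, at 0.42. The photoreceptor transcription factors Crx (-0.03) and Otx2 (0.06) lay near 0.

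**Figure D2:**
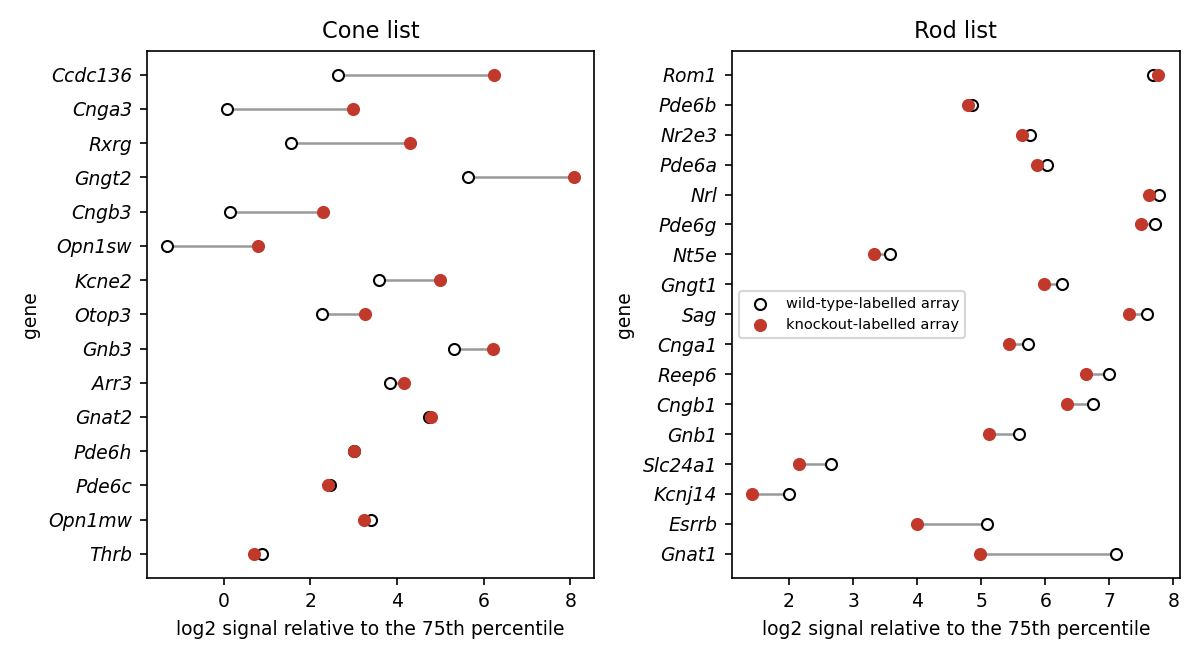
Log2 signal relative to the array's 75th percentile (horizontal axis) of each gene of the cone list (left) and of 17 of the 18 genes of the rod list (right), with open circles for the wild-type-labelled array and filled circles for the knockout-labelled array, 1 array each. Cone genes from Ccdc136 (3.61) to Gnb3 (0.89) lie higher on the knockout-labelled array while Gnat2 to Thrb nearly coincide, and every rod gene drawn except Rom1 (0.08) lies lower.

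Other retinal cell types were near level as groups. Bipolar cell genes had a median of 0.01 (percentile 89.0; -0.02 to 0.03 over the alternatives), although Gng13, a G protein gamma subunit of ON bipolar cells, was higher by 1.43 and the homeobox gene Irx6 by 0.86. Amacrine genes had a median of -0.02 (percentile 48.8; -0.02 to 0.001 over the alternatives), with Ptf1a, an amacrine and horizontal cell determinant, at least 2.17-fold higher by a bound but 1.40-fold under normexp. Horizontal cell genes (-0.03, percentile 49.99) and ganglion cell genes (-0.04, percentile 30.6) had no member 2-fold apart. Müller glia genes were slightly higher (median 0.06, percentile 99.7), led by Apoe (0.44) and the Notch target Hes1 (0.38). Genes of reactive gliosis had a median of -0.04 (percentile 36.5): the glial filament gene Gfap was at -0.05, Timp1 at 0.35, Lcn2 at -0.58, and A2m at least 2.07-fold lower by a bound (-0.32 under normexp).

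Among tissues next to the retina, lens genes were higher and pigment epithelium genes lower on the knockout-labelled array. The lens list had a median of 2.16, above all 10000 random lists, with 15 of 19 members at least 2-fold higher and none 2-fold lower; normexp brought the median to 1.54, with Crybb2 at 1.54, and took Crybb3 (0.99) and Cryba4 (0.96) below 2-fold. Crybb2 (2.80), Crygs (2.63), Crygc (2.35, with 3 probes from 2.06 to 2.43) and Cryaa (2.25) encode crystallins, the main soluble lens proteins. The lens water channel Mip was at least 5.79-fold higher by a bound (2.04-fold under normexp). Cryab, a crystallin made in many tissues, was at 0.08 (-0.02 with the mean over its probes) and the lens filament gene Bfsp2 at -0.15. Probes for the near-identical gamma crystallins Cryga to Crygf can share signal, so their separate values are uncertain. Retinal pigment epithelium and pigment cell genes had a median of -0.39, below all 10000 random lists, with 11 of 13 lower; Pmel (-0.81) and Tyrp1 (-0.68) were the lowest and Best1 (0.15, but -0.05 under normexp) the highest. Red blood cell genes had a median of 0.32 (percentile 99.98), from Hbb-bt at 0.44 down to Slc4a1 at -0.52. Endothelial and pericyte genes had a median of -0.10 (percentile 2.12, or 2.94 without matching on signal), with Tek at -0.29 and Kcnj8 at 0.33, and microglia genes one of -0.07 (percentile 9.28), with Csf1r at -0.23.

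**Figure D3:**
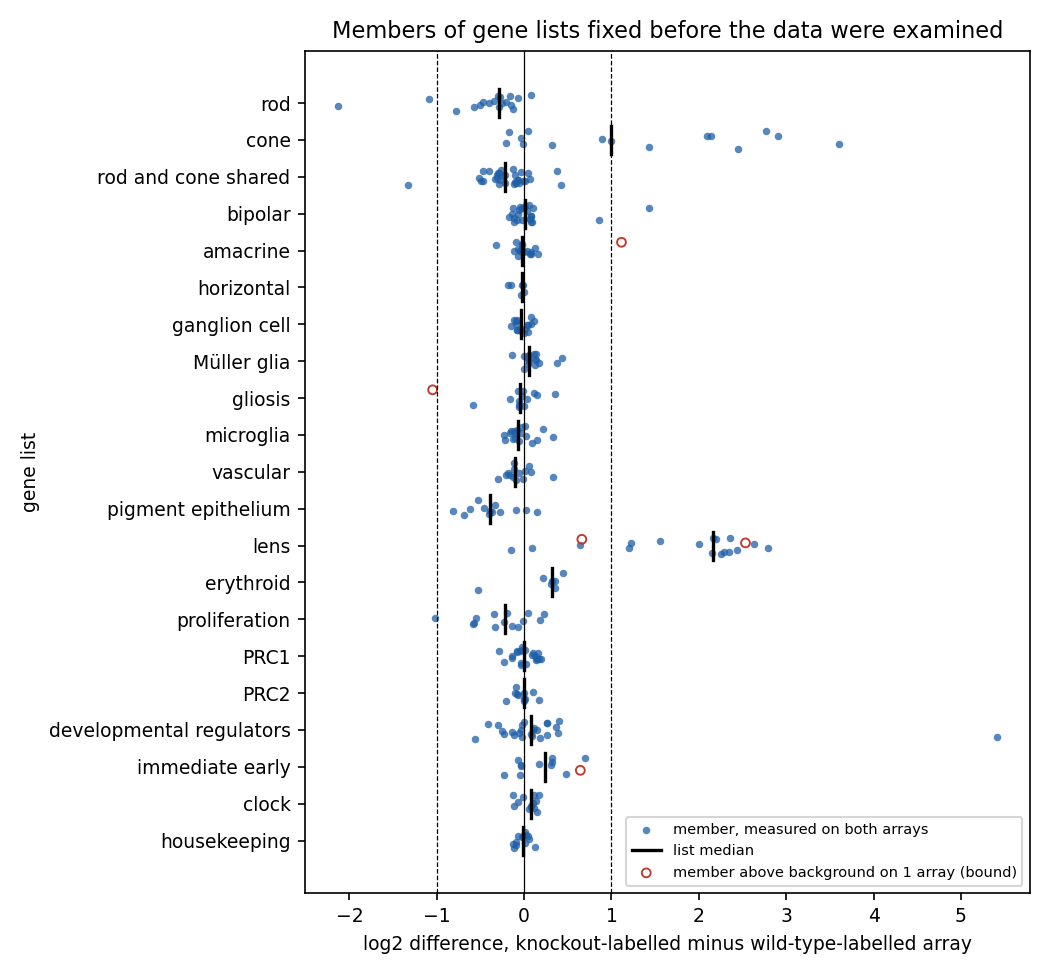
Log2 difference (knockout-labelled minus wild-type-labelled array, horizontal axis) of each member of 21 of the 25 gene lists, with 1 row per list. Filled points are genes measured on both arrays, open points are bounds for genes above background on 1 array, and black bars are list medians; the cone (0.997) and lens (2.16) medians stand to the right and the pigment epithelium (-0.39) and rod (-0.29) medians to the left.

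Components of the Polycomb complexes, which keep developmental genes silent, were near level. Complex 1 genes had a median of -0.005 (percentile 73.3; -0.005 to 0.01 over the alternatives), with the Samd7 relative Samd11 at 0.19 and Pcgf2 at -0.28. For complex 2 genes it was -0.01 (percentile 65.5; -0.01 to 0.02 over the alternatives), with the methyltransferase gene Ezh2 at -0.21. Of 59 non-retinal developmental regulators often under Polycomb repression, 25 were above background, and En2, a homeobox gene of the midbrain and hindbrain, was the only one 2-fold apart, at 5.41 or 42.5-fold higher (25.8-fold under normexp). The list's median of 0.08 (percentile 98.3) took the opposite sign with no filter on dim probes (-0.14) and was -0.0003 with the mean over probes. Cdkn2b was at 0.40 and Cdkn2a at -0.56. Only 4 of 39 Hox genes were above background (median -0.30, from -1.38 to -0.11 over the alternatives, percentile 23.3, or 1.21 without matching on signal), among them Hoxc13, at least 15.2-fold lower by a bound (3.42-fold under normexp). Germ cell genes had a median of 0.05 (percentile 75.3), with Hormad1 at least 2.87-fold lower by a bound (-0.30 under normexp).

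Proliferation genes were lower as a group, with a median of -0.21 (percentile 0.12; -0.11 under normexp), and Top2a, a topoisomerase of dividing cells, was 2.02-fold lower, but lay at -0.30 under normexp. Immediate-early genes were higher, with a median of 0.23 (percentile 99.99; 0.15 under normexp), with Egr1 at 0.70, Egr2 at least 0.64 higher by a bound and Fos at 0.48, while Nr4a1 was at -0.23. Circadian clock genes had a median of 0.08 (percentile 99.4), with Per1 at 0.17 and Arntl at -0.13. Unfolded protein response genes had a median of 0.02 (percentile 90.0), with Trib3 at -0.35. Sex-linked markers had a median of 0.08 (percentile 91.5): Xist (-0.12), Ddx3y (0.05) and Eif2s3y (0.12) were above background on both arrays at similar levels, and Uty was at 1.49 with its other probe at -0.24 and a value of 0.64 under normexp. Commonly used reference genes had a median of -0.01 (percentile 64.5; -0.05 to 0.03 over the alternatives), from Hprt (-0.13) to Sdha (0.13).

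Under the naming rule, the highest single genes on the knockout-labelled array after Insm2 (6.22) and En2, leaving aside the list members Ccdc136, Cnga3 and Crybb2 given above, were the processed pseudogene Hmga2-ps1 (4.35), Epha1, an ephrin receptor (4.16), the Rab GTPase regulator Tbc1d2 (3.79, with 3.88 in its other probe), Dnaic1, a dynein arm chain of motile cilia (3.73), and granzyme M, Gzmm (3.65). Bpifb6 (3.55), Fam83g (3.51), the smooth muscle cofactor Myocd (3.46), the anion exchanger Slc26a4 (3.36) and B3gnt7 (3.21) came next. The dim genes among them shrank under normexp, Epha1 to 2.36, Fam83g to 2.14, Slc26a4 to 2.06, Myocd to 2.83 and B3gnt7 to 1.23. Hmga2 itself was at -0.33, and signal shared with it leaves the value of Hmga2-ps1 (3.55 under normexp) uncertain. By bounds under the main values, the transcription factor gene Tal2 was at least 22.6-fold, Clec12b 8.34-fold and Ceacam18 7.86-fold higher. Aldoart2 (at least 19.0-fold) and Pou5f1 (at least 16.5-fold) have near-identical relatives in the genome, so their bounds are uncertain. Under normexp these 5 genes were between 1.003 (Ceacam18) and 2.12 (Tal2) higher on the log2 scale.

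Under the same rule, the lowest genes measured on both arrays were Ankle1 (-3.14, with -0.78 in its other probe), the zinc-finger gene Sp5 (-2.96) and Tinagl1 (-2.78, with -0.03 in its other probe). The motile cilium genes Cfap52 (-2.55) and Cfap126 (-2.27, with -2.06 in its other probe), Asb5 (-2.48) and the steroidogenic nuclear receptor Nr5a1 (-2.29) followed. Gnat3 was at -2.26; it belongs to the same alpha subunit family as Gnat1, and signal shared with Gnat1 was not excluded. The serotonin receptor Htr2a (-2.23), Olfr1417 (-2.20), the red cell membrane gene Epb42 (-2.15), Zfp952 (-2.07), the leukocyte tetraspanin Cd53 (-1.95) and the lymphatic growth factor receptor Flt4 (-1.94) completed the group. By bounds under the main values, the collagen gene Col6a6 was at least 38.5-fold lower, Prss43 10.8-fold, the POU factor gene Pou3f4 8.77-fold and Olfr1089 8.30-fold. The offset in normexp pulls the differences of dim genes toward 0, so for them its values cannot tell a true difference from a false one. Normexp ended the 2-fold call of Cfap52 (-0.97), Olfr1417 (-0.996), Epb42 (-0.63), Cd53 (-0.57), Flt4 (-0.45) and Pou3f4 (-0.94). It also left Ankle1 (-1.19), Sp5 (-1.06), Tinagl1 (-1.07), Asb5 (-1.02), Htr2a (-1.09), Prss43 (-1.17) and Olfr1089 (-1.16) little over 2-fold and Col6a6 at 6.78-fold. Gnat1, with a log2 signal of 7.10 on the wild-type-labelled array and 4.97 on the other, was the brightest of these lowest genes.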

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

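Probes that carry no gene name here were left out of the gene counts, and some of them differed strongly between the arrays, which is a signal in data outside the comparison of named genes. Of 13374 such probes above background, 320 (2.39%) were at least 2-fold higher on the knockout-labelled array and 427 (3.19%) at least 2-fold lower. At 8-fold there were 24 higher and 17 lower. Examples on the log2 scale were A_55_P2156404 (4.05) and A_55_P2148569 (3.50) on the higher side. On the lower side they were A_52_P273865 (-3.11) and A_55_P2072075 (-2.95). The last is less than 8-fold lower, so the examples are not the extremes of all counted probes. How many of the counted probes differ only by a bound is not given here. No explanation was tested for these probes.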

How the results depend on the processing

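The Samd7 difference stayed between 1.78 and 1.81, the rod median between -0.33 and -0.26 and the cone median between 0.98 and 1.02 under every alternative run for them; random lists without matching left the rod and cone percentiles as they were. Filters on dim probes could not move the rod and cone medians, because all members of both lists were above background on both arrays. The counts depended on the handling of dim spots. Against 252 higher and 218 lower genes, normexp on median signals gave 120 and 45 (120 and 44 of them in the main sets), genes above background on both arrays only 160 and 94, no filter 579 and 671, and mean signal at or above the median 69 and 14. The threshold alone gave 472 and 511 at 1.5-fold and 79 and 58 at 4-fold. Bounds drop out by construction where both arrays must be above background. The normexp offset of 50 shrinks the differences of dim genes by arithmetic, and the lower genes were the dimmer set. How much of their larger loss under normexp this accounts for was not tested. Quantile normalization gave 255 and 201, median centring 253 and 216, loess 257 and 199, the authors' values 253 and 215, and the mean over probes 255 and 218. The median of the non-retinal developmental regulators changed sign, from 0.08 to -0.14 with no filter and to -0.0003 with the mean over probes; the cause was not tested. Of 230 recomputed medians of lists other than rods and cones, 13 more moved by over 0.058, the median technical SD, and 16 in 6 lists changed sign, those of the developmental regulators included. Among 918 recomputed values of 153 named genes, 96 moved by over the technical SD at their signal, 78 of them under normexp. The sign changed in 12 values of 8 genes that were less than 2-fold apart (Calb1, Onecut3, S100a16, Best1, Mitf, Cryab, Ezh1 and Hoxa9) and in 0 values of the 67 genes at least 2-fold apart. Of those 67, 54 stayed 2-fold apart under normexp, where the fold of 35 moved over 1.5 times, and at least 65 under each other normalization and with the mean over probes; filters on dim spots were not run for single genes. Normexp on mean signals was not run, because the scanner files used here hold no such column; normexp on median signals and the filter on mean signal were chosen after seeing the data. No paired analysis was possible because each group has 1 array. Signal over background limits the dim genes: the technical SD was 0.37 below a log2 signal of -4 and 0.05 at 0 or more.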

Other observations

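The tests on the cone genes, on the lens genes, and on scaling, exchanged labels and probe position for Samd7 were chosen after the result was seen, as were the motile cilium, mitotic and non-crystallin lens lists and the single genes named in the next paragraph. The tests on the motile cilium and mitotic lists and on the neighbours of Samd7 were set before the values they use were seen, except that on the size of the neighbours' differences, chosen after their median was seen.

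Several genes outside the fixed lists were higher on the knockout-labelled array. Maf, a transcription factor that drives crystallin genes in lens fibre cells, was 6.39-fold higher (2.68 on the log2 scale). Fabp7, a fatty acid binding protein of glia and progenitors, was higher by 2.61, and Txnip, an inhibitor of thioredoxin, by 2.44. The clone-named gene A930009A15Rik, left out by the naming rule, was 66.8-fold higher, whereas Insm1, the close relative of Insm2, was at 0.22.

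Motile cilium genes were lower as a group on the knockout-labelled array. Cfap52 (-2.55), Cfap126 (-2.27), Cfap221 (-1.85), Dynlrb2 (-1.79) and Dnaic2 (-1.62) prompted the question, and Dnaic1 went the other way at 3.73. In a list of other motile cilium genes, 31 of 42 were lower, with Pifo at -0.91, Enkur at -0.90 and the ciliogenesis regulator Foxj1 at -0.71. Others were higher, among them Cfap161 (at least 3.30-fold) and Rfx2 (at least 2.22-fold) by bounds, Tekt4 (0.95) and Cfap46 (0.75), and Dnah5 was the only member at least 2-fold lower, by a bound. The median was -0.15, at percentile 0.07 of matched random lists (at most 0.78 under the alternatives), and -0.08 under normexp, which is in line with a joint shift of this gene group; whether it lies in the retina or in attached tissue was not tested. Mitotic genes beyond the fixed proliferation list were lower in 25 of 33 cases, with Kif11, which prompted the question, at -1.72, but their median of -0.10 lay at percentile 4.88, with alternatives on both sides of 2.5, from 0.04 under normexp and 1.76 with the mean over probes to 5.36 under loess and 10.1 with no filter, so a joint shift of these genes stays open.

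A stretch of donor-strain chromosome around a targeted gene could raise the number of differing genes there. Among the 50 measured genes on each side of Samd7, 3 were at least 2-fold apart (3%), against 2.95% of genes array-wide. The ratio of 1.02 shows no excess of 2-fold genes among these neighbours. So few genes could hold only a small part of the 2-fold differences array-wide, whatever the ratio. It does not bear on a longer stretch or on smaller differences.

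Part of the cone program was several-fold higher on the knockout-labelled array. A larger share of cone cells as the whole cause would raise cone genes about alike, yet 7 of 15 were at least 2-fold higher while 5 lay below 0.25. The interquartile range of their differences was 2.28, wider than in all 10000 matched random lists (95% of which lay between 0.05 and 0.20). That comparison adds little, because it was chosen after the spread had been seen and random lists hold mostly near-level genes. A loss of rods large enough to raise cone genes this much would raise the other retinal cell types too. The highest of the bipolar, amacrine, horizontal, ganglion and Müller medians was 0.0587, far below the cone median. That highest value was the Müller median, at percentile 99.7 of matched random lists, so a small loss of rods is not excluded. Scaling and background correction left the cone median at 0.98 or more. Filters on dim probes could not move it, because all 15 cone genes were above background on both arrays. A change within photoreceptors that goes with the genotype stays open as a hypothesis; it may act on Cnga3, Rxrg, Gngt2 and Opn1sw without acting on Gnat2 or Pde6h, and 1 array per genotype offers no test of it.

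Lens genes were higher on the knockout-labelled array while pigment epithelium genes were lower. Signal shared among gamma crystallins A to F could not produce this alone, since the other 9 crystallins had a median of 2.15. Lens material carried over at dissection cannot be told apart from crystallin expression in the retina. Of 11 non-crystallin lens genes outside the fixed list, 2 (18.2%, exact 95% binomial interval 2.28% to 51.8%) were higher by 0.5 or more, Lgsn (1.27) and Lctl (0.73). The interval treats these genes as independent draws, which a hand-picked list on 1 pair of arrays does not give, so it measures no sampling spread. Birc7 (0.42) and Grifin (0.42), both dim, lay just under the cut-off. In all, 6 of the 11 were higher by any amount, while Foxe3 was at least 3.55-fold lower by a bound. The median of the 11 genes was 0.13 (percentile 97.9), and with the 4 genes shared with the fixed list, Mip, Lim2, Bfsp1 and Bfsp2, it was 0.18 (percentile 99.7). Expression of crystallins in the retina, for example through Maf, stays open and untested.

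The Samd7 signal was 3.44-fold higher on the array labelled knockout. Scaling and background correction left the difference at 1.78 or more. A linked chromosome segment from another strain stays open: the median of the neighbours was -0.0526, inside the range set in advance against it, but strain differences can go both ways. Without regard to direction, the neighbours held no excess of 2-fold genes (ratio 1.02), yet their median size of difference, 0.12, lay at percentile 99.7 of matched random lists, so these values do not decide. By the range set in advance alone the segment would be set aside. Leaving it open rests on the measure of size, added later, and on the blindness of a signed median to differences in both directions. The random lists were drawn from the whole array and not from runs of neighbouring genes, so the percentile cannot show anything particular to this region. An exchange of the labels cannot be told apart from a probe outside the deleted part: both columns of the authors' value table (2 of 2) match their own scanner files, which leaves an exchange before scanning open, and only 1 probe is named Samd7. If the probe does lie outside the deletion, a transcript that persists from the altered gene at a higher level may account for the value, which was not tested.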
